A study of Mus musculus with 3 samples.

How the data were processed

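Total RNA of 3 cultures of mouse pluripotent stem cells was hybridised to Affymetrix Mouse Gene 2.0 ST arrays, 1 array per culture. Per the labels' protocols, all 3 cultures were grown in N2B27 medium and differed in the factors added to it. RNA was isolated on columns with DNase digestion and labelled as sense-strand DNA with the GeneChip WT PLUS kit, per the series' design text. The series' design text names GeneSpring GX 11.5 for the analysis, and the submitters' processing notes name RMA, which corrects the background, quantile-normalises the arrays and summarises the probes of a probe set.

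The deposited table held 1 value per probe set and array. From the values, these were intensities on a linear scale, with a lowest value of 18.9, 19.0 and 19.1 and a highest of 11409.6, 11623.3 and 11453.0 on the Activin+PD, 2i and mEpiSC arrays. A log2 scale had been assumed when the comparisons were set, so log2 of each deposited intensity was taken first and nothing else was changed. The similar lowest value on every array leaves open whether a constant was added before deposit, which is not given in the sources used here. A constant of that kind would make the fold differences of dim genes smaller than they were before it was added. Quantile normalisation by the submitters also makes the arrays' distributions alike, so a difference in total RNA per cell is not visible in these values.

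Of 33793 probe sets, 23521 were paired with 1 gene symbol in the platform annotation, 1814 with several and 8458 were not listed there. No gene was named from a probe set with several symbols. Symbols were updated through Entrez identifiers for 23328 probe sets, and 22180 genes remained. The 1082 genes with 2 or more probe sets were represented by the probe set with the highest mean over the 3 arrays. Genome coordinates were not used, and chromosomes were assigned to genes through Entrez identifiers.

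The arrays' number, 1 per group, limits the precision, so no p-value, standard error or replicate spread was computed and no difference was tested. Differences were log2 values of the first-named array minus the second. Background on each array was the 95th percentile of 1405 probe sets of olfactory and vomeronasal receptor genes, an intensity of 45.4 for Activin+PD, 48.1 for 2i and 47.5 for mEpiSC. For the gene counts, a gene was compared where the higher of the 2 arrays was above its background, and it was counted as apart where it also differed at least 2-fold. List members and the genes of each chromosome were compared where either array was above its background. Probe set error was estimated from 620 genes with more than 1 probe set above background, as the standard deviation of the disagreement between probe sets of a gene divided by the square root of 2. It was 0.24 on the log2 scale for Activin+PD minus 2i, 0.36 for mEpiSC minus 2i and 0.33 for mEpiSC minus Activin+PD. That spread covers the error of probe sets and not the variation between cultures. Unchanged arrays were simulated 100 times with a spread of 0.22 per array, to see how many genes would be counted and shared with no change.

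A gene not above background on the dimmer array of a comparison has only a bound there, so its difference is given as "by at least", the log2 value of the brighter array minus the background of the dimmer one. No difference is given where both were below background. Such genes were counted and entered list medians and ranks with their measured values, and the counts and medians with each value below background raised to it were taken as an alternative.

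The 29 gene lists, the rule for named genes, the thresholds and the alternatives listed at the end, except the 2 named there as later, were chosen before the data were examined. The lists covered pluripotency states (core, naive, and primed and formative), signalling (Activin/Nodal targets and pathway components, BMP, Wnt, FGF/ERK and JAK/STAT3 targets), lineages (primitive streak, definitive endoderm, primitive and extraembryonic endoderm, neuroectoderm, trophectoderm), fibroblast markers, 2-cell-like markers, germline genes repressed by DNA methylation, the DNA methylation machinery, epithelial and mesenchymal genes, glycolysis, oxidative phosphorylation, cholesterol synthesis, proliferation, p53 targets, stress response, imprinted genes, housekeeping genes and cell line identity. Of 576 listed members, 530 were matched to a gene on the array. For each list the median difference over compared members was taken with its 95% binomial interval over members, and its percentile was found among 10000 random lists of equal size matched on mean expression in 20 bins. A list was said to stand apart at a percentile of at most 2.5 or at least 97.5. The percentile describes these 3 arrays, and genes are not replicates. A gene can belong to several lists. The DNA methylation list holds genes that add methylation, such as Dnmt3b, and genes that oppose it, such as Prdm14. Its median therefore gives no direction for DNA methylation.

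Genes were named by a fixed rule. In each comparison it took the 10 genes with the largest difference in each direction among counted genes, leaving out predicted or unnamed gene models, small RNA genes and receptor genes. It also took up to 4 members with the largest difference in each list, and a set of 20 marker genes regardless of value. Of that set, T was not analysed here because no probe set with 1 symbol named it.

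The calculation was tested on simulated data made from the Activin+PD minus 2i comparison with all 22180 genes. Of 100 genes changed 4-fold, 99 were counted, and of 100 genes changed 1.5-fold, 12 were counted, as were 21 unchanged genes. A list of 20 genes shifted by 0.5 was found at 0.45, and 9 of 200 unshifted lists fell outside the percentile limits. Those lists were drawn at random with independent errors, so they do not show how the percentile behaves for lists whose members vary together.

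Alternatives were quantile normalisation of the 3 arrays once more, centring each array on its median, removal of a lowess trend with a span of 0.3, no filter on dim genes, a filter at the array median, thresholds of 1.5-fold and 4-fold, the mean of a gene's probe sets, lists without members of other lists, and random lists not matched on expression. Subtraction of 16 from each value before log2, a constant that some RMA implementations add, and raising each value below its array's background to that background were chosen after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.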

Results

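Gene expression was measured in 3 cultures of mouse pluripotent stem cells on 1 array each. Mouse embryonic stem cells (mESCs) of the established line EB3 made up both of the mESC cultures, and the mouse epiblast stem cells (mEpiSCs) had been induced from EB3 mESCs. In the Activin+PD culture, mESCs were kept for 64 days with 20 ng/ml Activin A, a TGF-beta family ligand that signals through SMAD2/3, and 2 µM PD0325901, a MEK inhibitor that blocks ERK activation. In the 2i culture, mESCs were kept for 34 days with 2 µM PD0325901 and 2 µM CHIR99021, a GSK3 inhibitor that stabilises beta-catenin. The mEpiSCs, which stand for the primed state of the post-implantation epiblast, were grown with 20 ng/ml Activin A and 12 ng/ml bFGF, for a time not given in the sources used here. The median intensity was 50.9 on the Activin+PD array, 51.2 on the 2i array and 51.9 on the mEpiSC array, and 13774, 13359 and 13673 of 22180 genes were above background. There were no replicates, so "higher" and "lower" describe these 3 arrays and no difference was tested against the spread between cultures. Where a gene was not above background on its dimmer array, only a bound on the difference is given, as "by at least".

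The first comparison asked how mESCs kept with Activin A in place of the GSK3 inhibitor differed from mESCs in 2i. Naive pluripotency genes were at similar levels in both, with 20 of 22 members within 2-fold and a list median of 0.28 (95% interval over members 0.038 to 0.37). Of 16 Activin/Nodal targets, 5 were at least 2-fold higher in Activin+PD and the list median was 0.39 (0.13 to 1.07), led by Lefty1 at 6.25-fold and a log2 difference of 2.64. Targets of Wnt/beta-catenin signalling were lower, with a list median of -0.57 (-0.92 to -0.14), led by Cdx2 at -2.80 and Axin2 at -1.96. Of 14022 genes compared, 193 were at least 2-fold higher and 115 at least 2-fold lower in Activin+PD, together 2.20%.

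Zfp42, a naive marker also called Rex1, had a log2 level of 11.45 in Activin+PD and 11.18 in 2i. Tfcp2l1 stood at 10.26 and 10.21, Esrrb at 7.22 and 7.18, and Klf4 at 8.03 and 8.29, all transcription factors of the naive network. Calcoco2 was the 1 naive list member at least 2-fold higher, by 2.09, and Gbx2 the 1 at least 2-fold lower, at -1.07, with a second probe set at -0.49. Prdm14, a repressor of FGF signalling and DNA methylation, was higher by 0.97 and Pecam1 by 0.70. The naive list median lay above all 10000 random lists. Among 15 core pluripotency genes, 14 were within 2-fold and the median was 0.23 (0.027 to 0.58; percentile 99.99). Nanog stood at 12.33 and 12.07, Sox2 at 11.24 and 11.01, and Pou5f1 at 8.09 and 8.24 in Activin+PD and 2i. Tdgf1, the Nodal co-receptor, was the core member at least 2-fold higher, by 1.30, followed by Dppa2 at 0.996 and Utf1 at 0.95 among those within 2-fold.

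The median of the Activin/Nodal targets lay above all 10000 random lists. Lefty1 and Lefty2, secreted antagonists of Nodal, were higher by 2.64 and 2.22, Tdgf1 by 1.30 and Pmepa1 by 1.06. Smad7, the inhibitory SMAD, was at 8.95 in Activin+PD and 7.90 in 2i. The 20 receptors, ligands and other components of the pathway had a median of -0.023 (percentile 39.2; 0.0031 without members of other lists), with Tgfbr3 at -2.50 and the Activin receptor gene Acvr1b at -1.20. Of 21 Wnt targets, 5 were at least 2-fold lower and 1 higher, and all 10000 random lists had a higher median. Cdx1 stood at -1.93 and Sp5 at -1.44, and the second probe set of Axin2, a feedback gene of the pathway, gave -1.03. The FGF/ERK list had a median of 0.14 (-0.24 to 0.45; percentile 99.2), with 21 of 24 members within 2-fold. Its member Dusp6, an ERK phosphatase, was higher by 2.56 (a second probe set was not above background on any array), whereas Epha4 and Ccnd1 were at -1.30 and -1.06. Spry4, another feedback inhibitor of ERK, stood at 5.98 in Activin+PD and was not above background in 2i. JAK/STAT3 targets had a median of -0.10 (percentile 6.70), with Pim1 at 1.12 and Socs3 at 6.21 and 6.41, and BMP targets a median of 0.036 (percentile 68.9; -0.037 without members of other lists), with Smad6 at 0.81 and Id1 at 5.63 and 5.72.

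The primed and formative list had a median of 0.22 (-0.40 to 0.49; percentile 99.98) with members on both sides. Otx2, a transcription factor of the post-implantation epiblast, was higher in Activin+PD by at least 2.23 and Fgf5 stood at 7.08 against 5.60, whereas Nkx1-2 and Wnt8a were at -3.20 and -1.79. A dim second probe set of Nkx1-2 gave -0.43. None of 16 primitive streak genes was 2-fold apart (median 0.039, percentile 68.8; -0.031 with values below background raised to it and -0.036 without members of other lists), the largest difference being 0.96 for Fgf17. The streak gene T, also on the Wnt list, was not analysed in any comparison. Definitive endoderm genes had a median of 0.087 (percentile 83.9; 0.37 over 6 members not in other lists, percentile 99.5), with Gpc4 at 1.53, Prdm1 at 1.17 and Trh at -1.50. The primitive and extraembryonic endoderm list had a median of 0.14 (-0.10 to 0.54; percentile 98.9), with the laminin genes Lama1 at -1.65 and Lamb1 at 1.33. Neuroectoderm genes had a median of 0.082 (percentile 88.2), with Olig3 at -1.62 and Tubb3 at 1.32, and trophectoderm genes 0.099 (percentile 90.2), with Gata3 at 1.56, whose second probe set gave 0.18. Fibroblast markers, which would show feeder cells, had a median of 0.026 (percentile 65.2; -0.025 without the filter and -0.029 without members of other lists) with 0 of 14 members 2-fold apart. Epithelial genes had a median of 0.0052 (percentile 56.6), which was slightly negative after quantile normalisation or median centring and without the filter. Mesenchymal genes had a median of 0.12 (-0.15 to 0.35; percentile 97.6), with the integrin gene Itga5 at 1.68.

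Germline genes that DNA methylation represses had a median of 0.42 (0.15 to 1.13), above all 10000 random lists. In this group 6 of 21 members were at least 2-fold higher and 1 lower, led by Rhox5 at 3.53, Mael at 1.73 and Dazl at 1.28, with Tex11 higher by at least 1.73. With values below background raised to it, 5 members were higher. The DNA methylation machinery had a median of 0.13 (-0.28 to 0.55; percentile 97.52), which turned to -0.064 over 7 members (percentile 26.7) without members of other lists, with Dnmt3a at 0.71 and Dnmt3b, at 8.95 against 9.54, at -0.60. The list of 2-cell-like markers had a median of 0.24 over 7 members (percentile 97.69), with Zscan4c at 0.51. That median was 0.12 over all 15 members without the filter, and it no longer stood apart with values below background raised to it (0.12, percentile 93.5). Cholesterol synthesis genes had a median of 0.37 (0.22 to 0.53; percentile 99.99) with 0 of 15 at 2-fold, led by Fdps at 0.72 and Dhcr7 at 0.70. Glycolysis genes had a median of 0.092 (-0.16 to 0.18; percentile 98.05), with the lactate exporter gene Slc16a3 at 1.68, and oxidative phosphorylation genes -0.027 (percentile 39.3). Proliferation genes had a median of 0.021 (percentile 83.0), with the cyclin gene Ccnd2 at 3.37. The medians of p53 targets, stress response, imprinted and housekeeping genes were -0.062, 0.082, 0.057 and -0.097, at percentiles 17.3, 95.1, 85.8 and 5.55, with Cdkn1a at -0.81, Xbp1 at 0.56, Mest at 1.05 and B2m at -0.73.

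Over all genes, the largest positive difference was that of Ddr2, a collagen receptor, at 4.13 or 17.6-fold. Its log2 level in 2i, 5.61, was just above the background of 5.59. Rhox5, Ccnd2, Crmp1 at 3.20, Actn3 at 2.85, Fgf15 at 2.65, Lefty1, Dusp6 and Aard at 2.51 followed, and Hesx1 was higher by at least 1.99. The second probe set of Fgf15 gave 0.13. Below Nkx1-2, the lower genes that the naming rule took were Cd109 at -2.98, Pglyrp1 at -2.83, Cdx2, the GDNF family receptor gene Gfra3 at -2.72, Foxi3 at -2.63 and Tgfbr3. Dmgdh, Arhgap20 and Ct55 were lower by at least 5.64-fold, 5.63-fold and 4.17-fold. The probe set spread was 0.24 in this comparison, smaller than in the simulated differences. In 100 simulations of unchanged arrays, 25.8 genes were counted on average and at most 42. With 16 subtracted from each value, 295 genes were at least 2-fold higher, and the percentiles of the DNA methylation, mesenchymal, glycolysis, 2-cell-like and definitive endoderm lists crossed their limit under some alternatives.

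**Figure D1:**
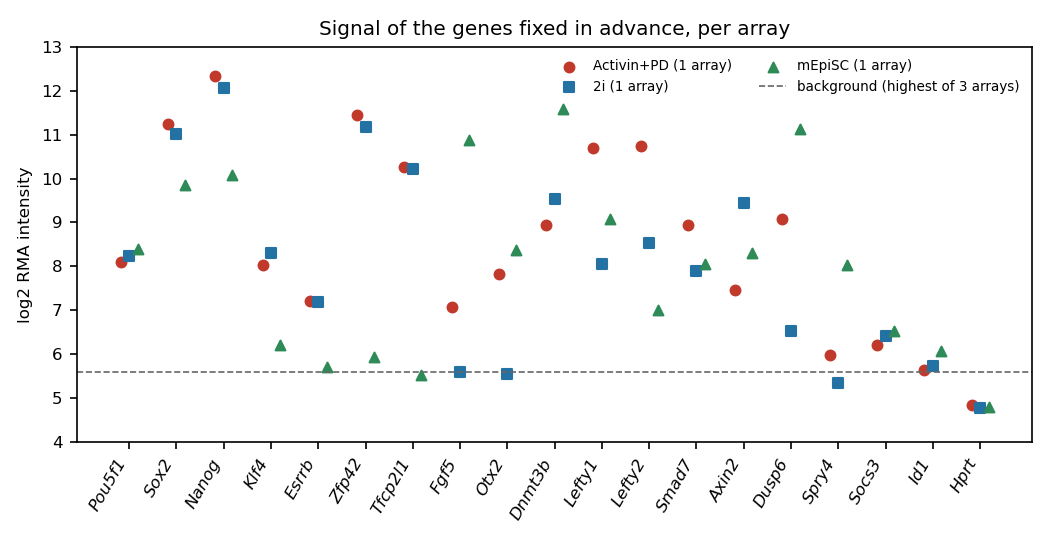
Log2 RMA intensity (y axis) of the marker genes fixed in advance (x axis), with 1 point per array (circles Activin+PD, squares 2i, triangles mEpiSC) and a dashed line at the highest of the 3 arrays' backgrounds. Zfp42 stood at 11.45, 11.18 and 5.94 and Lefty1 at 10.69, 8.05 and 9.07 in Activin+PD, 2i and mEpiSC.

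The second comparison set primed mEpiSCs against naive mESCs in 2i. Naive pluripotency genes were far lower in mEpiSCs, with 18 of 22 at least 2-fold lower and a median of -3.13 (-3.88 to -1.17), with Zfp42 at -5.24 and the nuclear receptor gene Nr0b1 lower by at least 4.49. Primed and formative genes were higher, with 13 of 23 at least 2-fold higher and a median of 1.33 (0.70 to 2.81), led by Fgf5 at 5.28 or 38.8-fold. The level of Fgf5 in 2i was just above background. FGF/ERK feedback genes, epithelial genes and definitive endoderm genes were higher too. Of 14223 genes compared, 644 were at least 2-fold higher and 705 at least 2-fold lower in mEpiSCs, together 9.48%.

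Fbxo15 and Tfcp2l1, further naive members, were lower by at least 4.56 and 4.64. Klf4 was at 6.21 in mEpiSCs and 8.29 in 2i, and Esrrb at 5.69 and 7.18. The naive list median lay below all 10000 random lists. Core pluripotency genes went both ways, with a median of -0.15 (-1.85 to 0.88; percentile 5.42), 2 of 15 higher and 5 lower. Pou5f1 stood at 8.39 in mEpiSCs and 8.24 in 2i, Sox2 at 9.85 and 11.01, and Nanog at 10.08 and 12.07, while the growth factor gene Gdf3 was at -3.89, Rex2 at -3.66 and Tdgf1 at 2.44. On the primed list, whose median lay above all 10000 random lists, Dusp6 was higher by 4.61, Igfbp3 by 3.45 and the Activin antagonist gene Fst by 3.05. Otx2 was higher by at least 2.78, and Dnmt3b, a de novo DNA methyltransferase, stood at 11.60 against 9.54.

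FGF/ERK genes had a median of 1.09 (0.62 to 2.11), above all 10000 random lists, with 14 of 25 at least 2-fold higher and 1 lower. Dusp4 was higher by 3.19, Spry2 by 2.77 and Spry4 by at least 2.43. Activin/Nodal targets had a median of 0.24 (-0.32 to 1.24; percentile 98.5), with 7 of 17 higher, among them Fgf8 at 1.93 and the secreted antagonist gene Cer1, higher by at least 4.15. Lefty1 was at 9.07 in mEpiSCs and 8.05 in 2i, Lefty2 at 7.01 and 8.53, and Smad7 at 8.06 and 7.90. Activin pathway components had a median of 0.13 (percentile 90.0), with Tgfb1 at 1.33 and Fstl1 at -1.68. Wnt targets had a median of -0.26 (-0.52 to 0.28; percentile 0.23), with Notum at -2.81, Cdx2 at -2.73, Axin2 at -1.13 and the receptor gene Fzd7 at 2.20. Lgr5 was higher by at least 1.37 on the probe set used, while its other probe set was close to background in mEpiSCs and not above it in 2i. The second probe set of Axin2 gave -0.83 and that of Notum was lower by at least 0.91. BMP targets had a median of -0.10 (percentile 7.53), with Id2 at 2.69, Id4 at -2.48 and Id1 at 6.06 against 5.72. JAK/STAT3 targets had a median of -0.13 (percentile 8.83; 0.097 without members of other lists), with the receptor genes Il6st at -2.07 and Lifr at -1.76, and Socs3 at 6.52 against 6.41.

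Lineage genes were higher in part. Of 18 primitive streak genes, 8 were at least 2-fold higher and 0 lower (median 0.29, percentile 99.2), led by Mixl1 at 3.37, Lhx1 at 2.70, Wnt3 at 2.68 and Eomes at 2.38. Of 12 definitive endoderm genes, 7 were higher and 0 lower (median 1.14, 0.13 to 1.76), with Foxa2 at 1.76 and Gata6 higher by at least 2.83-fold. The primitive and extraembryonic endoderm list stood at 0.12 (percentile 82.3), with Lamb1 at 1.74 and Foxq1 higher by at least 2.59, whose second probe set gave 0.18. Neuroectoderm genes stood at 0.10 (percentile 71.4), with Nes at 1.92 and Olig3 lower by at least 2.07. Trophectoderm genes had a median of -0.33 (percentile 0.41; -0.16 over 17 members without the filter) and a mean of the opposite sign, 0.020, with Cdx2 at -2.73 and the keratin genes Krt18 and Krt8 at 2.41 (second probe set 1.85) and 1.82. Fibroblast markers had a median of 0.082 (percentile 60.1), with Mmp2 at 1.52 and Tagln at 1.41.

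Epithelial genes had a median of 1.37 (0.54 to 2.36), above all 10000 random lists, with 11 of 19 at least 2-fold higher and 0 lower. Esrp1, a splicing regulator of epithelial cells, was higher by at least 3.48, Epcam by 3.23 and the claudin gene Cldn6 by 2.99. Mesenchymal genes had a median of 0.48 (-0.34 to 1.395), with 8 of 17 higher, such as Tpm1 at 2.17, and Fn1, which encodes fibronectin, at -2.52. Germline genes had a median of -0.84 (-1.41 to -0.33) with 7 of 17 at least 2-fold lower, among them Rpl10l, Dazl and Ddx4, lower by at least 3.50, 2.16 and 1.58. With values below background raised to it, that median was -0.42 with 5 members lower, and it was -0.42 over all 26 members without the filter. The DNA methylation machinery had a median of -0.44 (-1.82 to 0.028; percentile 0.16), with 1 of 12 at least 2-fold higher and 4 lower. Dnmt3b was higher by 2.05, whereas Tet2 stood at -3.62, Dnmt3l at -1.82 and Prdm14 was lower by at least 2.30. Over the 7 members not in other lists, the list median was -0.15 (percentile 11.9). The 2-cell-like list stood at -1.58 over the 6 members compared but at -0.14 over all 15 without the filter, with Zscan4e, of a family of near-identical genes, lower by at least 2.62. Cholesterol synthesis genes had a median of 0.98 (0.56 to 1.15), with 7 of 15 at least 2-fold higher, led by Lss at 1.54, Fdps at 1.39 and Cyp51 at 1.39. Glycolysis genes had a median of 0.18 (-0.041 to 0.44; percentile 97.47), with 2 of 20 at least 2-fold higher and 4 lower, among them Slc16a3 at 2.74 and Pfkp at -2.46. Oxidative phosphorylation genes had a median of -0.21 (-0.25 to -0.019; percentile 0.75), with Cox6b2 at -1.31. Stress response genes had a median of 0.27 (percentile 99.7), with Nqo1 at -1.93 and Hspa1b at 1.26. The medians of proliferation genes, p53 targets, imprinted genes and housekeeping genes were -0.13, -0.020 (0.0055 with no filter or without members of other lists), 0.12 and 0.10, at percentiles 2.85, 32.5, 85.3 and 77.7, with Ccnd2 at 2.31, Perp at 2.45, Grb10 at 2.58 and B2m at 1.01 (0.99 after lowess removal).

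Among the higher genes above background on both arrays, Dusp6, Epha1 at 4.50, Sema6a at 4.41, Enpp3 at 4.40 and Fndc3c1 at 4.23 followed Fgf5. St6gal2, the zinc transporter gene Slc39a8 and Cnn1 were higher by at least 4.38, 4.36 and 3.51. Zfp640 and Zfp981, not above background in mEpiSCs, were lower by at least 6.27 and 5.24, and the lower genes above it included Jam2 at -5.53, Pla2g1b at -4.85, the basement membrane gene Nid1 at -4.35 (second probe set -3.60) and Uba1y at -4.26. Zfp640 and Zfp981 belong to a family of similar zinc finger genes whose probes may not tell members apart. The spread of differences over genes was 0.67 against 0.35 in the first comparison, and the probe set spread was 0.36. At most 40 genes were counted in 100 simulations of unchanged arrays, whose simulated differences had less spread than 0.36. Without members of other lists, the Activin/Nodal target, primitive streak and DNA methylation lists no longer stood apart, and the glycolysis list reached its limit with the mean of probe sets and with values below background raised to it.

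The third comparison, between mEpiSCs and Activin+PD mESCs, set against each other the cultures that both received Activin A. Naive genes were lower in mEpiSCs, with 19 of 22 at least 2-fold lower and a median of -3.38 (-4.15 to -1.49), with Zfp42 at -5.51 and Calcoco2 lower by at least 5.30. Epithelial and FGF/ERK genes were higher, with medians of 1.17 (0.53 to 2.17) and 0.98 (0.46 to 1.92). Germline genes were lower, with 14 of 21 at least 2-fold lower and a median of -1.48 (-2.42 to -0.58). Of 14383 genes compared, 516 were at least 2-fold higher and 773 at least 2-fold lower in mEpiSCs, together 8.96%.

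Primed and formative genes had a median of 1.26 (0.56 to 2.57), with 14 of 23 at least 2-fold higher and 1 lower, led by Fgf5 at 3.80, Fst at 3.65, Cldn6 at 3.14 and the kinase gene Pim2 at 2.76. The naive members Nr0b1 and Fbxo15 were lower by at least 4.80 and 4.89. Core pluripotency genes had a median of -0.24 (-2.08 to 0.30; percentile 1.12), with Gdf3 at -3.71, Rex2 at -3.50 and Nanog at -2.25. Activin/Nodal targets did not stand apart, with a median of -0.088 (percentile 19.6), 3 of 17 higher and 3 lower. Over the 10 members not in other lists the median was -0.37 (percentile 2.74). On the whole list, Cer1 was higher by at least 4.23, with Lefty2 at -3.74 and Fgf8 at 1.69. Wnt targets had a median of 0.44 (0.063 to 0.89; percentile 99.99), with 4 of 22 at least 2-fold higher, such as Lef1 at 1.26 and Dkk1 at 1.19, and Notum at -2.67 (at least 0.86 lower on its second probe set). BMP targets had a median of -0.28 (percentile 0.43; -0.15 with values below background raised to it), with Id2 at 2.22, and JAK/STAT3 targets -0.028 (percentile 28.8), which was slightly positive after median centring, with the mean of probe sets or without members of other lists, with Klf4 at -1.81. The pathway component list had a median of 0.23 (percentile 98.8), with Pcsk6 at -2.01, but -0.0053 without the members of other lists.

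On the FGF/ERK list, 12 of 25 genes were at least 2-fold higher and 0 lower in mEpiSCs, led by Spry2 at 3.17, Dusp4 at 2.82 and Spred1 at 2.45, with the immediate early gene Egr1 higher by at least 2.67. Of 19 epithelial genes, 13 were higher and 0 lower, led by Epcam at 3.48 and Cldn6 at 3.14, with Cldn7 higher by at least 2.51. Primitive streak genes had a median of 0.28 (percentile 98.9; 0.15 and percentile 93.2 with values below background raised to it), with 7 of 18 higher, led by Mixl1 at 3.40 and Lhx1 at 2.98, and definitive endoderm genes 0.83 (percentile 99.99), with Krt19 at 1.92. Mesenchymal genes stood at 0.58 (-0.50 to 1.21) with 6 of 17 higher and 2 lower, among them Twist1 at 1.46 and Fn1 at -2.37. Rhox5 at -3.41 was among the lower germline genes, as were Dazl and Mael, lower by at least 3.45 and 2.31, and the list median lay below all 10000 random lists. With values below background raised to it, 12 germline genes were lower. The DNA methylation list had a median of -0.40 (percentile 0.27), with Tet2 at -3.76, Dnmt3b at 2.65 and Prdm14 lower by at least 3.27. Over the 7 members not in other lists, that median was -0.24 (percentile 5.48). The 2-cell-like list stood at -1.72 over the 7 members compared but at -0.17 over all 15 without the filter, with Zscan4e lower by at least 3.13. Cholesterol synthesis genes had a median of 0.60 (0.31 to 0.86) with 0 of 15 at 2-fold, led by Cyp51 at 0.93. Oxidative phosphorylation and proliferation genes stood at -0.16 and -0.14 (percentiles 1.85 and 1.30), with Cox7a1 at -0.90 and Ccnd2 at -1.06. Fibroblast markers had a median of 0.17 (percentile 86.3), with Tagln at 1.29.

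No other list stood apart, with medians of 0.041 for primitive and extraembryonic endoderm (negative after lowess removal, with no filter or without members of other lists), 0.19 for neuroectoderm, -0.052 for trophectoderm (0.031 with no filter and -0.91 over the 6 members not in other lists), 0.13 for glycolysis, -0.061 for p53 targets, 0.038 for stress response, 0.064 for imprinted and 0.14 for housekeeping genes. The means of the neuroectoderm, trophectoderm, glycolysis, p53 and stress lists had the opposite sign to their medians in this comparison. That was also the case for the BMP, neuroectoderm, trophectoderm and imprinted lists in the first comparison, and for the neuroectoderm and p53 lists in the second. Among the largest differences, Fndc3c1, Epha1 and Slc39a8 were higher in mEpiSCs by 4.60, by 4.58 and by at least 4.45, St6gal2 by 4.47, Psors1c2 by 4.05, the lipoxygenase gene Alox15 by 3.68 and Fabp5 by 3.82, with its 3 other probe sets at 2.37, at least 2.02 and at least 3.85. Kcnj3 was higher by 4.05, and by at least 0.70 on its second probe set. In Activin+PD, St6gal2 was close to background, as were Fabp5 and Kcnj3 on the probe sets used. Jam2 stood at -5.74, and Zfp640, Zfp981, Sohlh2, Ddr2 and Pramel30 were lower by at least 5.89, 5.37, 4.76, 4.18 and 3.76. At most 39 genes were counted in 100 simulations of unchanged arrays. The probe set spread was 0.33, larger than in the simulated differences. Under some alternatives the primitive streak, DNA methylation, oxidative phosphorylation, proliferation and pathway component lists no longer stood apart, and the trophectoderm list did so without members of other lists.

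**Figure D2:**
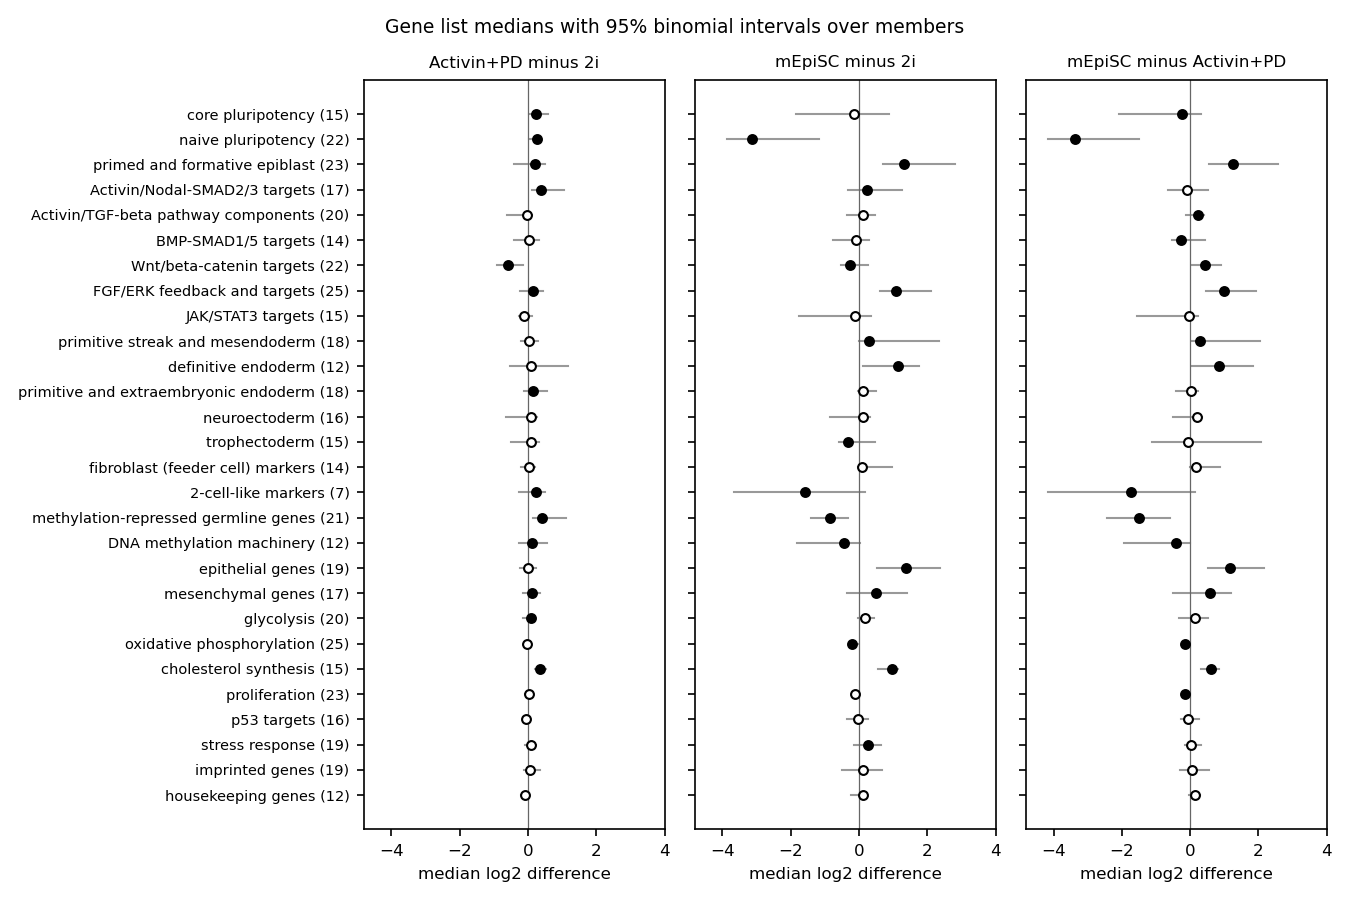
Median log2 difference of each gene list (x axis) in the 3 comparisons (panels), with 95% binomial intervals over members as lines and in brackets the number of members compared, the highest of the panels where it differed. Filled points lay outside the central 95% of 10000 matched random lists, such as naive pluripotency at 0.28, -3.13 and -3.38.

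The last comparison asked whether Activin+PD mESCs lay nearer to 2i mESCs or to mEpiSCs, over the genes that set the other 2 arrays apart. Of 644 genes higher in mEpiSCs than in 2i, 541 (84.0%) lay nearer to 2i in Activin+PD on the log2 scale, and the median gene stood 15.9% of the way to mEpiSC. Of 705 genes lower in mEpiSCs, 607 (86.1%) lay nearer to 2i, at a median of 9.37% of the way. Together 1148 of 1349 genes (85.1%) lay nearer to 2i. Correlations across genes, which are not independent replicates, were 0.974 between Activin+PD and 2i, 0.904 between mEpiSC and 2i and 0.907 between mEpiSC and Activin+PD. Some genes were apart from 2i in the same direction in both other arrays. Among 13724 genes compared in both, 176 were at least 2-fold higher in Activin+PD and 550 in mEpiSC, and 67 were so in both, such as Otx2, Dusp6, Tdgf1, Ccnd2 and Pmepa1. Of 115 and 705 lower genes, 72 were lower in both, such as Cdx2, Gfra3 and Arhgap20. Independent lists of 176 and 550 genes and of 115 and 705 genes would share 7.05 and 5.91 genes, and simulated unchanged arrays shared at most 3 and 5. With 1 array of 2i cells, the shared array cannot be split, so part of the excess may come from it.

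**Figure D3:**
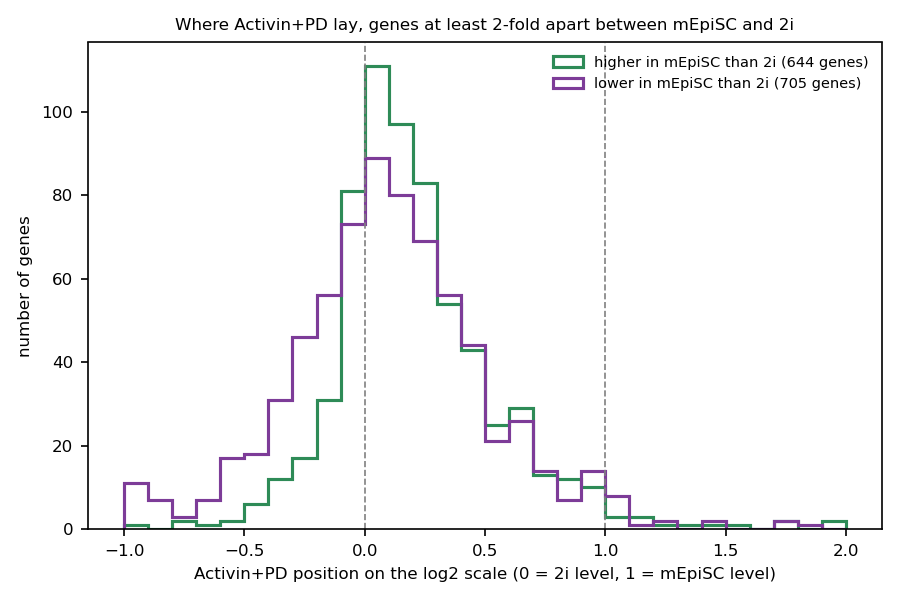
Position of Activin+PD between 2i (0) and mEpiSC (1) on the log2 scale (x axis) for the genes at least 2-fold apart between mEpiSC and 2i, as the number of genes per bin (y axis), with genes beyond either end of the axis in its last bin. Of the 644 higher genes (green), 84.0% lay nearer to 2i, and of the 705 lower genes (purple), 86.1%.

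The genes of the cell line identity list were too few above background for a median. Hprt was below background on all 3 arrays, at log2 levels of 4.83, 4.77 and 4.79 in Activin+PD, 2i and mEpiSC, as were Kdm5d and Xist. The Y-linked genes Eif2s3y and Uty stood at 9.16 and 7.87 in Activin+PD, 9.06 and 7.82 in 2i, and 8.43 and 7.08 in mEpiSC.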

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

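Of the alternatives, the subtraction of 16 from each value and the raising of values below background to it were chosen after the results were seen, and the others were planned. Under renewed quantile normalisation, median centring, lowess removal, the mean of probe sets, no filter on dim genes and a filter at the array median, all 6 counts of genes stayed within 1.5 times the values reported. With 16 subtracted, 295 genes were higher in Activin+PD than in 2i instead of 193, and the other 5 counts stayed within 1.5 times. With values below background raised to it, 188 genes were higher and 109 lower in Activin+PD than in 2i, 604 and 662 in mEpiSC than in 2i, and 488 and 729 in mEpiSC than in Activin+PD, and 66 and 67 were shared. At 1.5-fold, 637 genes were higher and 359 lower in Activin+PD than in 2i, 1351 and 1455 in mEpiSC than in 2i, and 1256 and 1574 in mEpiSC than in Activin+PD. At 4-fold, the counts were 20 and 18, 154 and 181, and 115 and 202. A change of threshold alters these counts by construction. The share nearer to 2i among genes lower in mEpiSC was 82.9% at 1.5-fold instead of 86.1%, a set that takes in smaller differences, and that share lay between 84.6% and 87.3% under the other alternatives.

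Without members of other lists, the median of Activin pathway components in mEpiSC minus Activin+PD was -0.0053 instead of 0.23 and that of the DNA methylation machinery in Activin+PD minus 2i was -0.064 instead of 0.13, over the fewer members left. Among lists that stood apart, that choice also gave 0.73 instead of 1.26 for primed and 0.43 instead of 0.83 for definitive endoderm genes in mEpiSC minus Activin+PD, 0.62 instead of 0.39 for Activin/Nodal targets and 0.062 instead of 0.12 for mesenchymal genes in Activin+PD minus 2i, and -0.15 instead of -0.44 and -0.24 instead of -0.40 for DNA methylation machinery in mEpiSC minus 2i and minus Activin+PD. With the mean of probe sets, core pluripotency genes stood at -0.47 instead of -0.24 in mEpiSC minus Activin+PD. With 16 subtracted, primitive streak genes in that comparison stood at 0.44 instead of 0.28 and 2-cell-like markers in Activin+PD minus 2i at 0.36 instead of 0.24. Among lists that stood apart, the medians that the filter or background values moved by over 1.5 times are given with the results. Medians of other lists that moved so are not all given. After lowess removal, the median of oxidative phosphorylation genes in mEpiSC minus 2i was -0.27 instead of -0.21, and the cause was not tested. Of 84 list percentiles, 11 crossed a limit without members of other lists, 5 with values below background raised to it, 4 each with no filter, renewed quantile normalisation and unmatched random lists, 2 each with lowess removal and the mean of probe sets, 1 with 16 subtracted and 0 with median centring. The median of all genes stayed within 0.08 of 0 in each comparison under each scaling. Normalisation makes the arrays alike, so this does not show that total RNA was unchanged. Of 386 differences of named genes, 0 changed sign under the alternatives run for them. Most of these genes were named for the size of their difference, so few signs could turn. Use of a gene's other probe set alone was not among the alternatives. For Foxq1 in Activin+PD minus 2i, it gave -0.18, against at least 0.78 on the probe set used. By more than the probe set spread, 119 differences moved with 16 subtracted, 26 with values below background raised to it and 22 with the mean of probe sets. Signal near background limits the dim genes most, since a constant in the deposited values would shrink their differences.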

Other observations

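All tests in this part were chosen after the results they bear on had been seen, and so were the genes singled out in the next paragraph.

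Some of the genes that led the comparisons were high in Activin+PD and not in either other culture. Rhox5 differed by 3.53 from 2i and mEpiSC differed from Activin+PD by -3.41, and the same pair of differences was 2.85 and -2.39 for Actn3 and 2.51 and -3.23 for Aard. Ddr2 was higher in Activin+PD than in 2i by 4.13 and than in mEpiSC by at least 4.18, and the homeobox gene Hesx1 by at least 3.98-fold and 4.03-fold. Lefty2 stood at 10.75 in Activin+PD, 8.53 in 2i and 7.01 in mEpiSC, although the mEpiSC medium also held Activin A. Foxi3 was low in Activin+PD alone, with differences of -2.63 and 3.04. Other genes were high in 2i and alike in both Activin A cultures, where mEpiSC differed from Activin+PD by -0.026 for Pglyrp1 and 0.076 for Cdx2, and Arhgap20 was not above background in either. Crmp1 was higher than in 2i by 3.20 in Activin+PD and by 3.38 in mEpiSC. The Y-linked gene Uba1y was at -4.26 in mEpiSC minus 2i, when Eif2s3y and Uty, also Y-linked, were at -0.63 and -0.73.

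The 67 genes higher than in 2i in both other cultures were weighed against a share of mEpiSC-like cells in the Activin+PD culture. On the linear scale, 42 genes at least 8-fold higher in mEpiSC than in 2i stood at a median of 2.76% of the way to mEpiSC (95% interval 0.348 to 5.88), or 3.68% (0.978 to 5.88) with Activin+PD values below background raised to it, with Epha1 at -0.242%. The shared genes stood at 63.3% (54.5 to 83.0), but they were picked for being high in Activin+PD, so the gap between the 2 medians is no test. The 42 genes were chosen without the Activin+PD array, and their median limits cells with the profile of the mEpiSC array to a share of a few percent. That share of such cells is too small to account for most of the shared genes. The median does not limit primed cells whose ERK targets are held down by PD0325901, because the 42 genes include ERK list members such as Dusp6 and Dusp4. Fgf5, also higher than in 2i in both cultures, stood at 4.745%, within the interval of the 42 genes. Probe set error in the 2i array, drawn as normal errors of the pooled spread, gave at most 3 shared genes in 100 simulations. That argues against normal errors of that size, but not against a 2i culture that differed as a whole. Errors with heavier tails were not simulated and could share more genes. In Activin+PD minus 2i, the measured probe set error had a standard deviation of 0.24, but 0.16 when estimated from its median absolute deviation. Higher ERK target expression cannot be told apart, because the 14 ERK list members higher in mEpiSC had a median Activin+PD minus 2i difference of 0.25 with an interval from -0.27 to 0.77 that included 0. The presence of Activin A in both media, or the absence of CHIR99021 from both, may account for the shared genes, and neither was tested since the design holds 1 culture per medium.

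The higher germline genes in Activin+PD were set against a higher level of X-linked genes as a whole, since 6 of the 21 members are X-linked, with a median of 0.76. All 460 X-linked genes compared had a median of 0.092 (0.046 to 0.13), against -0.0094 for autosomal genes. The 15 autosomal members alone had a median of 0.42 (0.15 to 0.85), above that X-linked level, so it cannot be the whole cause. Lower expression of DNA methylation enzymes cannot be told apart, because 2 of 5 genes were lower by more than the probe set spread while others were not, with differences from -0.60 for Dnmt3b to 0.71 for Dnmt3a, and DNA methylation itself was not measured. The cultures also differed in length, 64 against 34 days, and in medium, and neither was tested.

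The genes apart between Activin+PD and 2i were also weighed against an extra copy of a whole autosome in most cells of 1 culture. Over 19 autosomes, the largest median difference was 0.042 in size, against a limit of 0.29 set at the square root of a 1.5-fold gain. A 1.5-fold gain also lies below the 2-fold threshold, so copy number by itself would place few genes among those counted. A gain in a small share of cells and a gain of part of a chromosome were not tested. Other differences that come with 64 against 34 days in culture were not tested either and could underlie some of the genes.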
